A study of Mus musculus with 2 samples.

How the data were processed

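Ileal tissue of wild-type C57BL/6 mice at postnatal day 21 was lysed and treated with nuclease, and ribosome-protected fragments were collected through a sucrose cushion, depleted of rRNA, amplified and sequenced on an Illumina Genome Analyzer, per the labels' protocols. There was 1 library from fed mice and 1 from mice fasted for 48 h. How many animals went into each library, and whether tissue was pooled, is not given in the sources used here. The deposited files hold the authors' raw read counts per gene symbol, not normalised. The tools cutadapt, Bowtie 1.1.2, STAR and HTSeq and the genome build mm10 are named, with no role or order, per the submitters' processing notes. The gene annotation, the strand setting and any length filter on footprints are not given in the sources used here, so reads of a gene and an overlapping or antisense gene cannot be told apart.

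Each file ends in totals of reads that were assigned to no gene, which were left out of library sizes and ratios. Reads given as overlapping no counted feature made up 13.4% of all counted reads in the fed file and 21.0% in the fasted file. Which features were counted is not given, so these reads need not lie outside genes. Reads aligned to several places made up 41.4% and 39.9%, and ambiguous reads 0.209% and 0.196%. Since reads aligned to several places were not assigned to genes, genes with many close copies or pseudogenes are counted too low or not at all. Of the 78 ribosomal protein genes in the files, 32 had no read in either library. The files list 22756 gene rows, of which 15676 had a read in at least 1 library. No gene row holds 0, and 7647 rows in the fed and 7827 in the fasted file are given as NA. These were read as 0 counts, since of the 1314 genes at NA in 1 library the median count in the other was 1 (at most 109). In the files 24 symbols had been turned into calendar dates, 4 of these rows repeating a name; they stayed in the totals and are not named. Symbols were matched to GENCODE vM21 (GRCm38, the assembly of mm10) for 21943 rows (96.4%), which gave gene identifiers, coordinates (1-based), coding lengths and base composition.

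Library sizes were scaled with TMM in edgeR 4.0.16 under R 4.3.3. With 1 library per group no test between conditions can be run, so edgeR was used for scaling only and no p-values are given. For each gene the fasted/fed ratio of scaled counts was given with a 95% exact interval (Clopper-Pearson, on the split of the gene's counts between the libraries). These intervals treat reads as independent molecules, and the libraries were amplified by PCR, so intervals and floors cover counting error only and not differences between animals. A gene was counted as measured with at least 30 counts summed over both libraries, and as higher or lower with a ratio of at least 1.5-fold and an interval excluding 1. A count of 0 allows up to 3 counts, which is 0.483 CPM in the fed and 0.617 CPM in the fasted library. The same counting functions were tested on simulated libraries drawn with sampling noise alone from the real gene means, with 200 measured genes changed. In the simulated libraries 11298 genes reached 30 counts. The changes were few and equally up and down, so the choice between TMM and plain CPM was not tested. For the fasted against fed comparison, intervals covered the true ratio for 95.7% of genes, 1.37% of unchanged genes were counted as higher or lower, and 62%, 94%, 98% and 100% of genes changed by 1.5, 2, 3 and 4 fold were recovered.

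Gene lists (47, for pathways, cell types and other tissue components) were fixed before the data were examined. For lists with at least 5 measured members, the median log2 ratio (0.5 counts added to each count) was set against 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. The percentile is the share of random lists with a lower median, and describes these libraries. Genes named in the text are Hes1, the 12 highest and 12 lowest ratios ranked by the interval bound nearest to 1 among genes with at least 100 counts (unnamed gene models, pseudogenes, small RNAs and histones left out), the 10 genes with most counts, and up to 3 members per list in its main direction with up to 2 in the other. A few best-known markers (Lyz1, Muc2, Lgr5, Lct, Sis, Atf4 and Rps6) were added to that rule before the data were examined, and another gene of the rule is not reported here. Genes chosen after their values were seen are named as such.

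Alternatives were plain CPM, median-ratio size factors (DESeq2 1.42.0), upper-quartile factors, TMM without ribosomal protein, mitochondrially encoded and the 20 most abundant genes, no minimum count or a minimum of 200, a 2-fold threshold, 99.9% intervals, 2 added counts, unmatched random lists, and means in place of medians. For the weighed explanations, medians were bootstrapped over genes (10000 draws), matched lists were drawn from the 100 genes nearest in coding length or GC share, and a coding sequence was called unique where its 28-base windows occur in no other annotated gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Translational efficiency was left out because no mRNA library was analysed here.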

Results

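Ribosome-protected mRNA fragments (footprints) were sequenced from the ileum, the last part of the small intestine, of wild-type C57BL/6 mice at postnatal day 21, around weaning. There was 1 library from fed mice and 1 from mice fasted for 48 h, so each condition had n = 1. A footprint is the piece of mRNA that a ribosome shields from nuclease, and the footprint count of a gene reflects both how much of its mRNA was present and how heavily that mRNA was translated. No matched mRNA library was analysed here, so these counts cannot be split into mRNA abundance and translation. The fed library held 5558620 footprints assigned to genes and the fasted library 5434252. Footprints assigned to genes made up 45.0% of the reads counted in the fed file and 38.9% of those in the fasted file. Reads overlapping no counted feature made up 13.38% in the fed file (95% exact Clopper-Pearson interval 13.36% to 13.40%) and 20.98% in the fasted file (20.957% to 20.9997%). Every difference given here is between these 2 libraries, not between conditions, and has no replicate check. The intervals on ratios cover counting error only, and no p-values were computed. Values in brackets after a gene are its fasted/fed log2 ratio and the 95% interval of that ratio.

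The comparison asks how the feeding state bears on translation of Hes1, a transcriptional repressor induced by Notch signalling that holds back the secretory cell fate, and of mucosal antimicrobial genes. Hes1 (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796, plus strand, mm10) had 194 counts in the fed and 141 in the fasted library. That was 31.2 and 29.0 TMM-scaled CPM (counts scaled to library size), a fasted/fed log2 ratio of -0.10 (95% interval -0.43 to 0.22), so no difference was detectable at this depth. With plain CPM, which divides by the total gene count alone, the log2 ratio was -0.43 (interval -0.75 to -0.11), a 0.743-fold level in the fasted library whose interval excluded 1. Of 24 measured genes of the Notch pathway and its targets, 4 were higher in the fasted library, 6 lower and 14 neither, and the median log2 ratio of -0.062 lay at percentile 35.2 of random lists. With plain CPM 2 were higher, 9 lower and 13 neither, at a median of -0.38. Lower members included Pofut1, which adds the O-fucose that Notch receptors carry (log2 ratio -1.04, interval -1.48 to -0.61), Adam10, a protease that cleaves Notch (-0.92, -1.09 to -0.76), and Atoh1, the secretory-lineage factor that Hes1 represses (-0.90, -1.25 to -0.56). Higher members included Notch4 (1.36, 0.66 to 2.08) and Ncstn, a subunit of gamma-secretase (0.77, 0.68 to 0.86), although Ncstn did not reach 1.5-fold with plain CPM (0.45).

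Antimicrobial genes split by kind. Of 14 measured Paneth cell products, the defensins and enzymes that crypt-base Paneth cells release, 9 were higher in the fasted library, 1 was lower and 4 were neither. The median log2 ratio was 0.70 (percentile 98.7), just above the random band, the middle 95% of random lists, which spanned -0.22 to 0.64. By the interval bound nearest to 1, the highest were Defa35 (2.39, 1.66 to 3.20), the defensin-like AY761184 (1.49, 1.41 to 1.57) and Pla2g2a (1.53, 1.04 to 2.03). Pla2g2a, a secreted phospholipase gene, is annotated as a polymorphic pseudogene, so its footprints do not show that a working enzyme was made. Defa26 was the lower member (-0.66, -1.003 to -0.33). Lyz1, Paneth cell lysozyme, had a log2 ratio of 0.0074 (-0.32 with plain CPM). Summed over members, Paneth products took 1.65% of fed and 1.60% of fasted gene counts. Such summed shares are of the total gene count, as in plain CPM, and are not TMM-scaled like the medians. Only 4 members were higher with plain CPM, and the list was within the random band when members needed 200 counts (median 0.65) or when the mean replaced the median (0.69). The Defa genes are near-identical copies, so their counts are uncertain. By contrast, of 18 measured genes of enterocyte and inducible antimicrobial defence, 8 were lower in the fasted library, 3 higher and 7 neither (median -0.60, percentile 0; within the band, at -0.27, with no minimum count). Duox2 (chromosome 2, 122279247 to 122298449), the hydrogen peroxide producing oxidase of the epithelial surface, was 18.0-fold lower (log2 ratio -4.17, -4.31 to -4.03). Its maturation factor Duoxa2, the adjacent gene (122298900 to 122302885), was 24.7-fold lower (-4.63, -4.92 to -4.35). Sprr2a3, an antibacterial small proline-rich protein, was also lower (-3.17, -3.71 to -2.68), as was Reg3b, an antibacterial lectin and among the 10 genes with most counts (-0.93, -0.95 to -0.91). Its relative Reg3g, chosen after its value was seen, had a log2 ratio of -1.40 (-1.44 to -1.36). Higher were Lcn2, which binds bacterial siderophores (2.16, 1.52 to 2.83), and Tlr5, the flagellin receptor (1.41, 0.41 to 2.49).

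**Figure D1:**
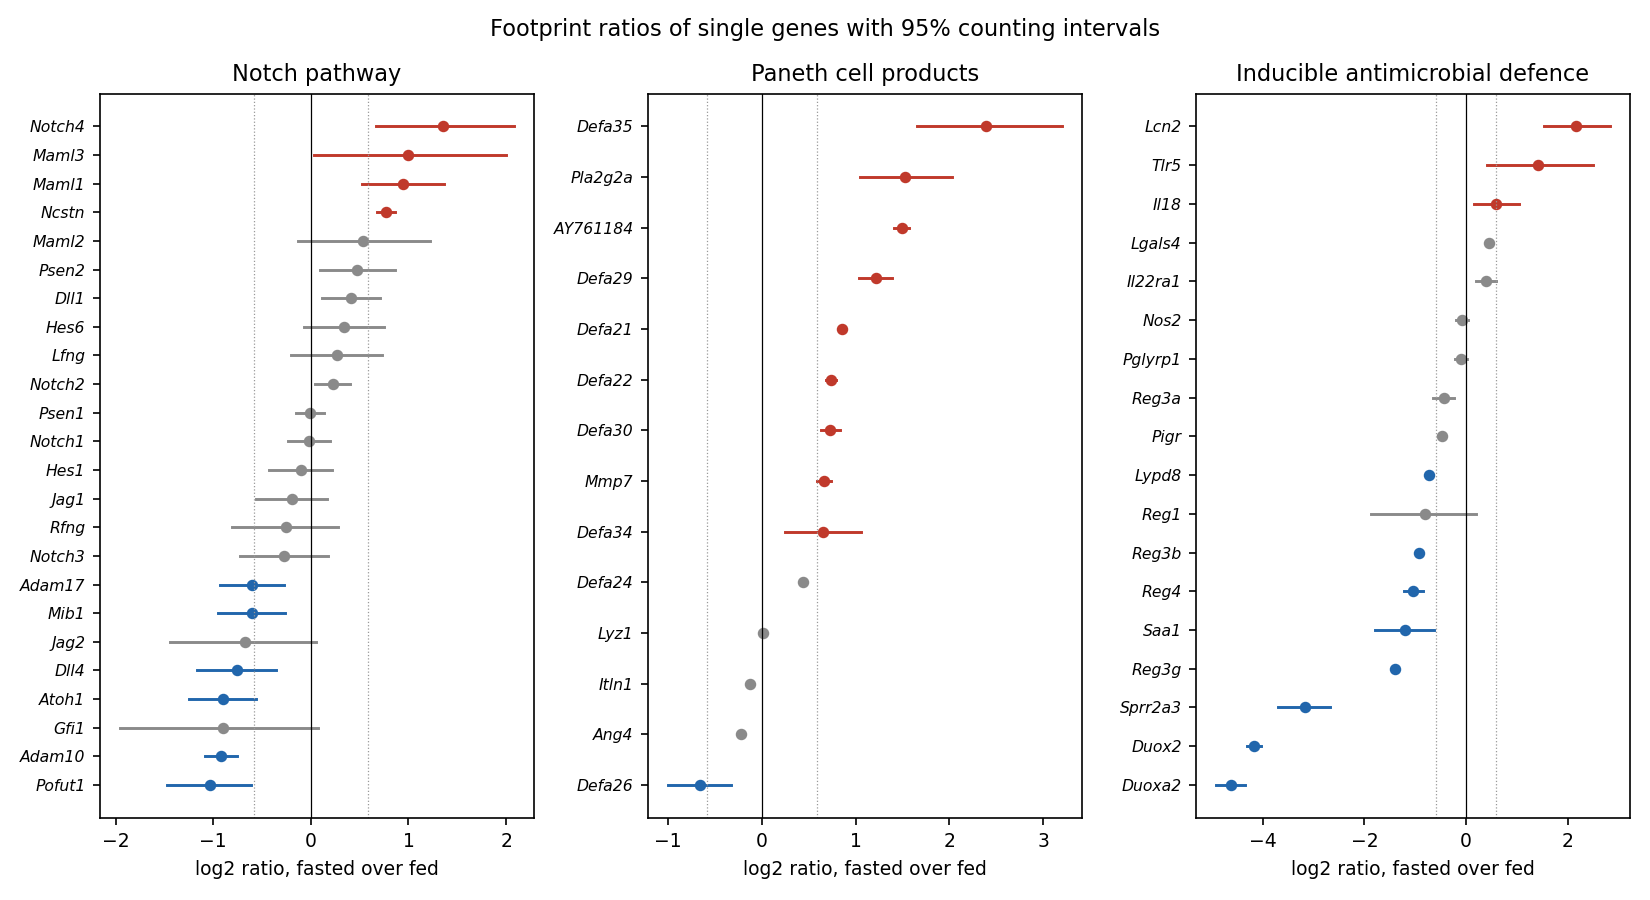
Log2 ratios (x axis, fasted over fed library, TMM-scaled) of the measured genes of the Notch pathway, Paneth cell products and inducible antimicrobial defence; lines are 95% exact counting intervals, dotted lines mark 1.5-fold, and red, blue and grey mark genes higher, lower or neither in the fasted library. Hes1 sits at -0.10 with an interval across 0 (-0.43, below 0, with plain CPM), and Duoxa2 and Duox2 lie lowest in the defence panel at -4.63 and -4.17.

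The other epithelial lineages differed in direction. Goblet cell products had 10 of 20 measured members lower in the fasted library, 0 higher and 10 neither (median -0.64, percentile 0). Muc2, the gel-forming mucin, was 2.40-fold lower (log2 ratio -1.26, -1.28 to -1.24), Agr2, a protein disulfide isomerase needed for mucin, had -2.21 (-2.31 to -2.10) and Clca1 -1.39 (-1.42 to -1.37), while Fcgbp, the gene with most counts in the data, had 0.15 (-0.17 with plain CPM). Tuft cell markers had 8 of 11 lower and 0 higher (median -0.99, percentile 0.06), among them Dclk1 (-1.29, -1.72 to -0.89). Enteroendocrine products had 9 of 19 higher and 0 lower (median 0.59, percentile 99.91), including Chga (1.49, 1.34 to 1.65); with plain CPM 5 were higher. Crypt stem cell markers lay within the random band (median -0.13, percentile 18.1), with 1 higher, 4 lower and 14 neither (7 lower with plain CPM). Among them Lgr5 had 0.18 (-0.071 to 0.43; -0.14 with plain CPM) and Olfm4 -1.74 (-1.82 to -1.67). Cell cycle genes had 39 of 47 members lower, 1 higher and 7 neither (median -1.05, percentile 0). Ccne2, a cyclin of the G1 to S transition (-2.87, -3.78 to -2.07), and Hells, a chromatin remodeller (-2.30, -2.84 to -1.81), were among the lowest, and Rrm2, a ribonucleotide reductase subunit, was the higher member (1.07, 0.81 to 1.33). Replication-dependent histones followed with 11 of 38 lower and 2 higher (median -0.33, percentile 0.5; within the band, at -0.23, with a 200-count minimum; 20 lower with plain CPM). Their genes are multicopy, so single values are uncertain.

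Across the 11333 genes with at least 30 counts in sum, 1956 were at least 1.5-fold higher in the fasted library with an interval excluding 1, 1962 were lower and 7415 were neither. Higher genes made up 49.9% of these calls, a near-even split that TMM favours because it sets the typical ratio near 1. Plain CPM moved every log2 ratio by -0.32 against TMM, the median of all genes included, and gave 1004 higher and 3536 lower genes, 22.1% higher. A smaller set reached 2-fold, with 935 higher and 1035 lower. The genes furthest apart are set out in the plot of both libraries. Among the higher ones were Pdk4, the kinase that shuts down pyruvate dehydrogenase (60.0-fold, log2 ratio 5.91, 5.64 to 6.19; 113 counts in the fed and 5300 in the fasted library), Pck1, which makes phosphoenolpyruvate in gluconeogenesis (44.5-fold, 5.48, 5.39 to 5.56; 1127 counts in the fed and 39184 in the fasted library), and the metallothioneins Mt2 (5.59, 5.29 to 5.92) and Mt1 (4.93, 4.76 to 5.10), which lie beside each other on chromosome 8. The rule also gave the drug-metabolising Cyp3a11, Cyp2b10 and Cyp4b1 (4.98, 5.17 and 4.09), the glucocorticoid-induced Zbtb16 and Fkbp5 (5.26 and 4.07), the lipoprotein lipase inhibitor Angptl4 (4.22), and the transporter Slc47a1 (4.39). Myot, a sarcomere protein, had 0 fed and 109 fasted counts, at least 46.5-fold higher against a floor of 3 counts in the fed library with the fasted count taken as it stands. The exact interval, which covers the counting error of both libraries, began at 37.2-fold. Among the lower ones, besides Duox2 and Duoxa2, were Pla2g4c, a cytosolic phospholipase (33.9-fold, -5.08, -5.36 to -4.82), S100g, the intestinal calcium-binding protein (-4.54, -5.87 to -3.47), and Gsdmc2, Gsdmc3 and Gsdmc4, neighbouring gasdermin genes on chromosome 15 (-5.50, -4.63 and -4.82). The Gsdmc genes are close copies, so the counts of each are uncertain. The rest were immunoglobulin variable segments, given with the B cell genes.

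**Figure D2:**
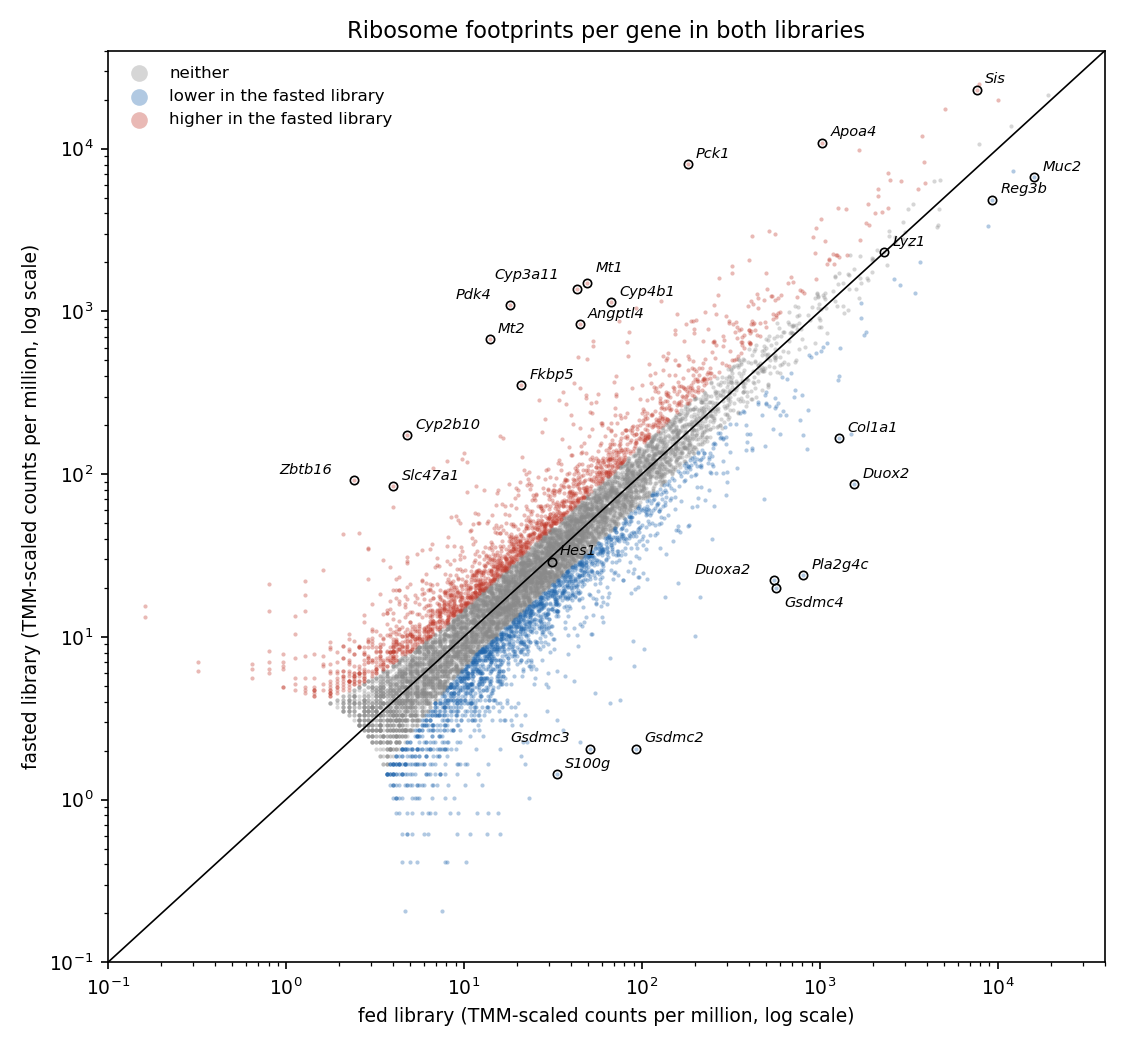
TMM-scaled footprint CPM of each gene with at least 30 counts in sum, fed library on the x axis and fasted on the y axis, both on log scales; genes with no read in 1 library are not drawn, the line marks equal levels, and red, blue and grey mark higher, lower or neither. Pdk4 and Pck1 lie 60.0-fold and 44.5-fold above the line, Pla2g4c and Duox2 lie 33.9-fold and 18.0-fold below it, and Hes1 lies on it within counting error under this scaling.

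Genes of glucose production, fat burning and low insulin were mostly higher in the fasted library. So were absorptive genes of the enterocyte, while smooth muscle and fibroblast markers were mostly lower. Gluconeogenesis had 8 of 10 members higher and 0 lower (median 2.004, percentile 100; 8 higher and 2 lower with plain CPM), with G6pc, glucose-6-phosphatase (3.62, 3.46 to 3.79), and Slc37a4, its substrate carrier (3.37, 3.20 to 3.55), beside Pck1. Fatty acid oxidation and ketogenesis, largely PPAR alpha targets, had 23 of 39 higher, 0 lower and 16 neither (median 0.75, percentile 100; 18 higher and 3 lower with plain CPM), including Acaa1b, a peroxisomal thiolase (3.96, 3.37 to 4.61). FOXO and low-insulin targets had 12 of 18 higher and 2 lower (median 1.55, percentile 100), with Klf15 (4.37, 3.56 to 5.30) and Txnip (2.41, 2.36 to 2.46) against Sesn3 (-1.62, -2.46 to -0.86). Glucocorticoid targets had the highest list median, 2.45 (percentile 100), with 11 of 14 higher and 0 lower. Circadian clock genes had 7 of 15 higher and 1 lower (median 0.63, percentile 99.92), with Per1 (3.41, 3.11 to 3.72), Cry2 (2.63, 2.28 to 2.99) and Nr1d1 (2.07, 1.91 to 2.22) higher and Bhlhe41 lower (-1.48, -2.93 to -0.23). Xenobiotic metabolism had 28 of 39 higher and 1 lower (median 1.21, percentile 100), the lower member being Cyp2c55 (-0.97, -1.25 to -0.70). Cyp3a11 and its relatives are paralogs, so reads shared between them leave single values uncertain.

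The lipid synthesis lists had medians below 0. Fatty acid synthesis had 6 of 15 members lower and 1 higher (median -0.51, percentile 0.17; 10 lower and 0 higher with plain CPM), with Me1, malic enzyme (-2.75, -3.60 to -2.002), Scd2 (-1.86, -2.11 to -1.62) and Fasn, fatty acid synthase (-1.72, -1.84 to -1.60), lower. Cholesterol synthesis and uptake had 11 of 24 lower and 1 higher (median -0.33, percentile 0.3), including Insig1 (-1.49, -1.96 to -1.04) and Sqle, squalene epoxidase (-1.06, -1.25 to -0.88). Glycolysis lay within the random band (median -0.21, percentile 4.29) with 2 higher and 3 lower (1 and 6 with plain CPM), but below it, at -0.43, with a 200-count minimum. Pkm, pyruvate kinase, was higher (1.11, 0.99 to 1.23) and Pfkl, a phosphofructokinase, lower (-0.67, -0.93 to -0.41). The urea cycle, citrulline and proline list was within the band at 0.30 (-0.019 with plain CPM), with 5 higher and 1 lower. Glul, glutamine synthetase, was higher (2.60, 2.42 to 2.79) and Odc1, ornithine decarboxylase, lower (-1.47, -2.73 to -0.37).

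Absorptive genes of the enterocyte were mostly higher in the fasted library. Brush border digestive hydrolases had 14 of 21 members higher and 0 lower (median 0.87, percentile 99.7) and took 5.32% of fed and 8.72% of fasted gene counts. Sis, sucrase-isomaltase (3.02-fold, 1.60, 1.58 to 1.61), Mgam, maltase-glucoamylase (1.79, 1.77 to 1.81), Lct, lactase (1.78, 1.74 to 1.82), and Treh, trehalase (1.98, 1.87 to 2.09), were all higher, while Anpep, aminopeptidase N, had 0.20 (-0.13 with plain CPM). Sugar and amino acid transporters had 18 of 23 higher and 2 lower (median 1.49, percentile 100), including Slc2a2, the basolateral glucose transporter (11.8-fold, 3.56, 3.42 to 3.70), and Slc2a5, the fructose transporter (2.50, 2.35 to 2.65). Lower were Slc6a14, an amino acid transporter (-3.89, -6.21 to -2.27), and Slc9a3, the sodium/proton exchanger (-0.94, -1.19 to -0.69). Lipid absorption and lipoprotein assembly had 20 of 26 higher and 0 lower (median 1.29, percentile 100), with Apoa4 (10.5-fold, 3.40, 3.36 to 3.44), Fabp1 (2.86, 2.66 to 3.07), Apoa1 (1.66, 1.65 to 1.68) and Apob (0.998, 0.98 to 1.01). Ileal bile acid and vitamin B12 handling had 9 of 12 higher and 0 lower (median 0.96, percentile 99.7; within the band, at 0.83, as a mean), including Abcc2 (1.90, 1.81 to 1.999), Fgf15, the bile acid induced hormone (1.46, 1.34 to 1.58), and Cubn, the vitamin B12 receptor (1.11, 1.09 to 1.13). Fabp6, the ileal bile acid binding protein, chosen after its value was seen, had -0.44 (-0.47 to -0.41). Genes of the suckling-period enterocyte had 6 of 12 higher and 0 lower (median 0.57, percentile 98.7). The higher ones included Lct and Cubn, both given above, and Dab2 (0.997, 0.65 to 1.35). Lct is in the hydrolase list too, so these lists are not separate. The suckling-period list was within the band with a 200-count minimum (0.62) or as a mean (0.58), and 3 members were higher with plain CPM. Smooth muscle and fibroblast markers were mostly lower in the same library, at medians of -0.72 and -1.02.

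Among genes of the translation machinery, ribosomal protein genes were mostly lower in the fasted library. Of 36 measured cytosolic ribosomal protein genes 31 were lower, 0 higher and 5 neither (median -1.02, percentile 0, middle 95% of random lists -0.30 to 0.23). Summed over the list, ribosomal protein genes took only 0.177% of fed and 0.067% of fasted gene counts. For 32 of the 36, less than 50% of the coding sequence was unique, so their values rest on the part of their reads that aligned to 1 place. Rps19 (-2.58, -3.47 to -1.80), Rps4x (-2.48, -3.76 to -1.40) and Rplp0 (-1.94, -2.37 to -1.54) were lowest by the interval bound nearest to 1. Another 32 of the 78 ribosomal protein genes in the files, Rps6 among them, had no uniquely assigned read in either library, since reads that align to several places were left out. Translation factors and other mRNAs with a 5' terminal oligopyrimidine tract had 13 of 27 lower, 1 higher and 13 neither (median -0.54, percentile 0; 20 lower and 0 higher with plain CPM), including Pabpc1, poly(A)-binding protein (-2.06, -2.36 to -1.77), Rack1 (-1.65, -1.79 to -1.52) and the elongation factor Eef1a1 (-1.51, -1.63 to -1.39). Components of the mTORC1 pathway, which senses amino acids, were within the band at 0.072 (-0.25 with plain CPM), with 7 of 36 higher and 4 lower against 4 and 9 with plain CPM. Eif4ebp1, a repressor of cap-dependent translation, was higher (1.32, 0.74 to 1.91). Targets of ATF4, the factor of the amino acid response, went both ways, 9 higher and 9 lower of 35 (6 and 16 with plain CPM), at a median of -0.22 (percentile 2.69). Ddit4, an inhibitor of mTORC1 signalling, was 12.04-fold higher (3.59, 3.41 to 3.78), Mthfd2 (-1.73, -2.62 to -0.93) and Psat1, of serine synthesis (-1.54, -2.23 to -0.91), were lower, and Atf4 itself had 0.14 (-0.35 to 0.63; -0.18 with plain CPM). Nuclear-encoded respiratory chain genes had 65 of 71 neither, 1 higher and 5 lower (median -0.012, percentile 7.12). With plain CPM 15 were lower, 0 higher and 56 neither (median -0.33). Cell cycle genes were mostly lower in the same library (median -1.05).

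Protein folding genes were mostly lower as well. The unfolded protein response and endoplasmic reticulum folding list had 15 of 22 members lower and 1 higher (median -0.82, percentile 0). Creld2 (-2.31, -2.81 to -1.84), Pdia4, a disulfide isomerase (-1.46, -1.59 to -1.34), and Hsp90b1, a luminal chaperone (-1.29, -1.35 to -1.24), were lower, and Herpud1, of endoplasmic reticulum associated degradation, was the higher member (2.61, 2.51 to 2.71). In the same library 15 of 17 B cell and plasma cell markers (median -1.14) and 10 of 20 goblet cell products (median -0.64) were lower, while Paneth cell products, also of a secretory cell, had a median of 0.70. Cytosolic heat shock proteins had 10 of 16 lower and 1 higher (median -0.99, percentile 0), with Hsph1 (-2.91, -3.22 to -2.62), Chordc1 (-1.98, -2.38 to -1.59) and Hsp90ab1 (-1.69, -1.76 to -1.62) lower. Autophagy and lysosome genes had 12 of 38 higher and 1 lower (median 0.38, percentile 99.5; 7 higher with plain CPM), including the mitophagy receptor Bnip3 (2.24, 1.21 to 3.42) and the cargo receptor Sqstm1 (1.24, 1.15 to 1.33). The list of p53 targets and cell death lay within the band at 0.29 (-0.030 with plain CPM; above it, at 0.75, as a mean), with 7 of 18 higher and 1 lower. Pmaip1 (4.02, 3.57 to 4.51) and Bbc3 (2.99, 1.61 to 4.71), both pro-apoptotic, and the cell cycle inhibitor Cdkn1a (1.88, 1.77 to 1.996) were higher. Immediate-early genes, which tissue handling also induces, had 8 of 20 higher and 1 lower (median 0.45, percentile 99.3; within the band, at 0.40, as a mean).

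Interferon, MHC and B cell genes were mostly lower in the fasted library, while the T cell and myeloid lists lay within the random band. The interferon response and MHC class I list had 20 of 31 members lower and 0 higher (median -1.16, percentile 0), including Zbp1, a nucleic acid sensor (-3.32, -4.36 to -2.44), Stat2 (-2.29, -2.71 to -1.89) and Oasl2 (-2.22, -2.54 to -1.90). All 8 measured MHC class II genes were lower (median -0.92, percentile 0.03), among them Ciita, the class II transactivator (-1.51, -1.99 to -1.04), and Cd74, the invariant chain (-0.95, -0.99 to -0.91). B cell and plasma cell markers had 15 of 17 lower and 0 higher (median -1.14, percentile 0), with Cr2, complement receptor of follicular B cells (-2.97, -4.07 to -2.03), Jchain, the joining chain of secreted IgA (-1.14, -1.22 to -1.05), and Igha, the IgA heavy chain (-0.73, -0.75 to -0.71), lower. Immunoglobulin variable segments went both ways, with 50 of the 86 with at least 100 counts lower, 15 higher and 21 neither (median -0.81, quartiles -1.92 and 0.15). The naming rule gave 5 of the lower ones, Igkv8-27 (-4.31), Iglv2 (-4.32), Ighv1-52 (-4.09), Ighv5-16 (-3.78) and Igkv15-103 (-3.61). Such segments are similar copies used by different B cell clones, so single values are uncertain. T and intraepithelial lymphocyte markers were within the band (median -0.41, percentile 7.48) with 4 of 17 lower and 1 higher (9 lower and 0 higher with plain CPM), and below it, at -0.87, with a 200-count minimum. Gzmb, a granzyme, was lower (-1.39, -1.86 to -0.93). Myeloid markers were within the band at 0.066 (-0.26 with plain CPM), with 1 higher and 3 lower of 19 (0 and 7 with plain CPM), Itgam being the lowest (-1.25, -1.52 to -0.98).

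Markers of the other cell types in ileal tissue differed in direction. Fibroblast and matrix genes had 16 of 24 members lower and 2 higher (median -1.02, percentile 0). The collagens Col3a1 (8.58-fold, -3.10, -3.20 to -3.000), Col1a1 (7.74-fold, -2.95, -3.06 to -2.85) and Col5a2 (-2.08, -2.33 to -1.83) were lower. Dcn, decorin (0.83, 0.76 to 0.90), and Pdgfra, a receptor of fibroblasts (0.72, 0.60 to 0.84), were higher, though neither reached 1.5-fold with plain CPM (0.51 and 0.40). Smooth muscle markers had 12 of 19 lower and 0 higher (median -0.72, percentile 0), including Actg2, enteric actin (-1.85, -1.94 to -1.75), and Tagln (-1.54, -1.69 to -1.40). Endothelial markers had 7 of 17 higher and 0 lower (median 0.45, percentile 99.0; 2 higher with plain CPM), with Pecam1 at 1.23 (0.99 to 1.47). Enteric neuron and glia markers had 8 of 13 higher and 0 lower (median 0.60, percentile 99.8; 3 higher with plain CPM), with Syt1 at 1.96 (1.25 to 2.73). Adipocyte markers went both ways, 4 higher and 3 lower of 10 (2 and 3 with plain CPM), at a median of 0.51 within the band, with Plin1 lower (-3.07, -4.43 to -1.95) and Pck1, an epithelial gene too, higher. Pancreatic acinar products had 4 measured members (0 higher, 1 lower), erythroid markers 3 (2 higher, 0 lower) and mitochondrially encoded proteins 0, too few for a median. Of the 44 lists given a median, 17 lay above, 16 below and 11 within the middle 95% of random lists.

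**Figure D3:**
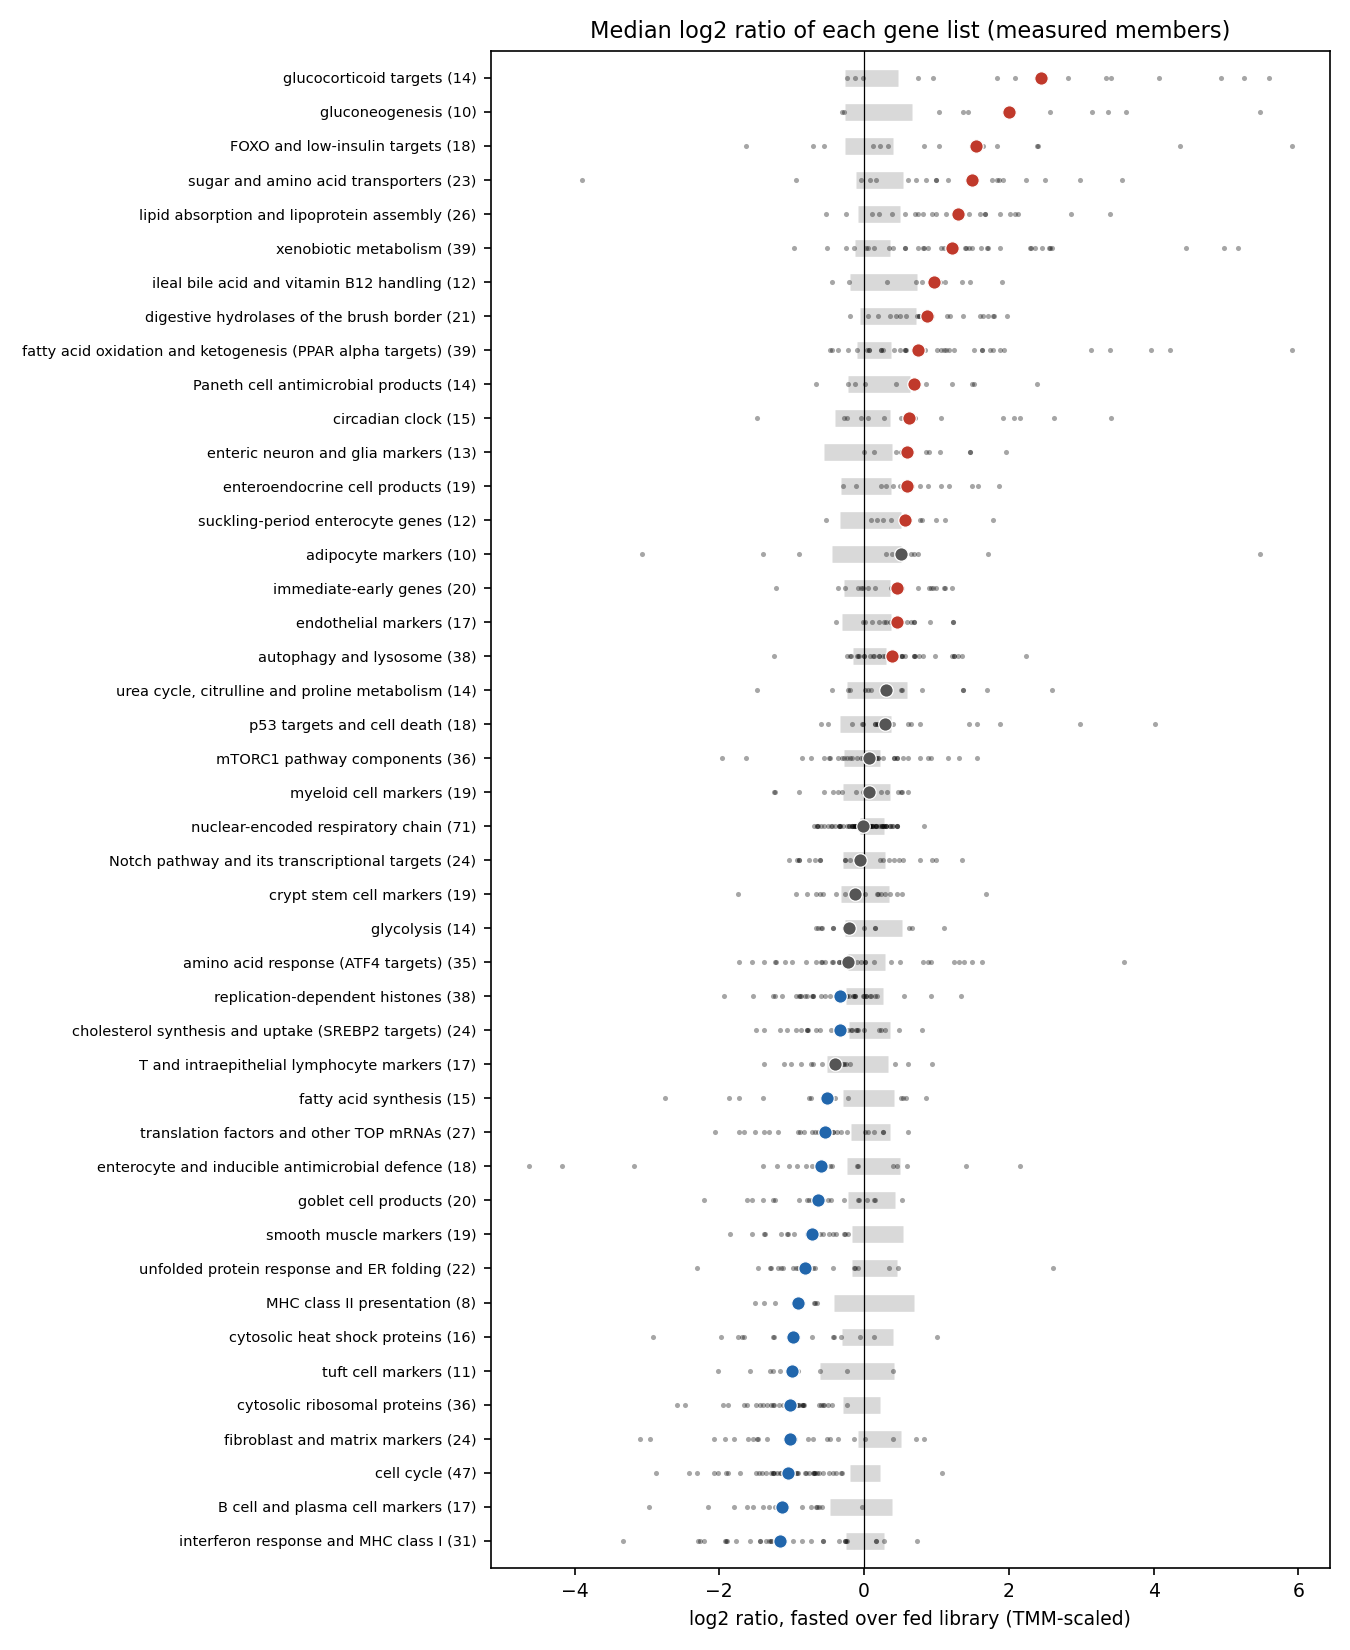
Median log2 ratio (x axis, fasted over fed library, TMM-scaled) of the measured members of 44 gene lists, with the number of measured members in brackets; grey bars span the middle 95% of 10000 random lists matched on expression, small points are members, and red, blue and dark points are medians above, below and within that band. Glucocorticoid targets lie highest at 2.45, and the interferon response and MHC class I list lies lowest at -1.16.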

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

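Reads that the deposited files count as overlapping no feature are given here because they enter no comparison of genes. They need not lie outside genes, since the features counted and the strand setting are not given. They made up 20.98% of all reads in the fasted file (95% exact interval 20.96% to 21.0%), 2931328 of 13973144, against 13.38% in the fed file, 1651853 of 12344331. With 1 library per group, these values do not show whether either share is unusual. Reads aligned to several places made up 41.4% and 39.9%, and ambiguous reads 0.209% and 0.196%. No explanation was tested, because the files give these reads as a single total per library.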

How the results depend on the processing

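The settings were chosen before the data were examined, except leaving out genes with no read in a library and leaving out immunoglobulin genes, which were added after. Leaving out a replicate was not possible with 1 library per group. Plain CPM in place of TMM, a shift of -0.32 on every log2 ratio, gave Hes1 -0.43 with an interval below 0, 1004 higher and 3536 lower genes, while the other 3 scalings left Hes1 with an interval across 0. The 200-count minimum gave 1187 higher and 892 lower genes, fewer being tested, and the 2-fold threshold 935 and 1035. Some lists crossed the edge of the random band. With the 200-count minimum the Paneth (0.65), suckling (0.62) and histone (-0.23) lists moved inside it, and the glycolysis (-0.43), T cell (-0.87) and ATF4 (-0.22) lists moved outside. With means, the Paneth (0.69), bile acid (0.83), suckling (0.58) and immediate-early (0.40) lists moved inside and the p53 list (0.75) outside. With no minimum the inducible antimicrobial list moved inside (-0.27). With 2 counts added the ATF4 (-0.22) and adipocyte (0.51) lists moved outside, as did the adipocyte list with TMM without abundant genes (0.51) and, with unmatched random lists, the adipocyte (0.51) and T cell (-0.41) lists. Beyond the fewer genes tested, the cause was not tested. Over all lists and settings 466 medians kept their side of the band, 9 moved outside and 8 inside. Of the 466, 5 changed sign, all within the band: with plain CPM the urea cycle (-0.019), p53 (-0.030), mTORC1 (-0.25) and myeloid (-0.26) lists, and with means the myeloid list (-0.11). Of the single named genes, 759 values kept their call and 17 lost it, and no called value changed sign. Depth limits genes with few counts, since 3 counts equal 0.483 CPM in the fed and 0.617 CPM in the fasted library.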

Other observations

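Several genes outside the lists and the naming rule stood far apart between the libraries, and all in this paragraph except Mt1 and Mt2 were chosen after their values were seen. Guca2b and Guca2a, the uroguanylin and guanylin peptides that drive intestinal fluid secretion, were higher in the fasted library (log2 ratios 2.57, interval 2.50 to 2.65, and 1.44, 1.37 to 1.498). Slc39a4, the zinc importer of the enterocyte, was lower (-1.76, -1.87 to -1.66), in the library where Mt1 (4.93) and Mt2 (5.59), which bind zinc, were higher. Mt1 and Mt2 are also members of the glucocorticoid target list, and a link to Slc39a4 was not tested. Slc46a1, the proton-coupled folate transporter, was lower (-2.50, -3.17 to -1.89). Cirbp, a cold-inducible RNA-binding protein, was 15.0-fold higher (3.91, 3.49 to 4.36), as were Ndrg1 (3.50, 3.37 to 3.62) and Cyp27a1, a sterol 27-hydroxylase (3.42, 3.19 to 3.66). Nfe2l2, which encodes the oxidative stress factor NRF2, was lower (-1.99, -2.17 to -1.81), as was Il1rl1, the receptor of interleukin 33 (-4.70, -7.01 to -3.11).

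Some factors that make collagen were lower in the fasted library with the collagens, again chosen after their values were seen. Serpinh1, the collagen chaperone, had a log2 ratio of -2.64 (-2.86 to -2.42), P4ha1, a prolyl hydroxylase subunit, -2.45 (-3.05 to -1.89), and Plod2, a lysyl hydroxylase, -1.39 (-2.08 to -0.74). Plod1 had 0.096 (-0.15 to 0.34), and Lox, which cross-links collagen outside the cell, was higher (2.06, 1.66 to 2.48).

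Explanations were weighed for 3 patterns, and the tests of cycling crypt cells and of a more proximal piece of intestine, and the split of the microvillus genes, were chosen only after the results were seen. A biological effect of fasting stays open for each pattern and was not tested, because fasting and library coincide. First, 31 of 36 ribosomal protein genes were lower in the fasted library (median -1.02). Reads shared with pseudogenes and other copies argue poorly as the whole cause, since the 4 genes whose coding sequence was at least 50% unique had a median of -1.07 (bootstrap interval -1.34 to -0.93), though 4 genes are few, and the other 32 had -1.02. Short coding sequences or GC share, each taken alone, are also argued against. Of the random lists matched on coding length 0 of 10000 had a median as low, and of those matched on GC share 0 of 10000. The similarly short respiratory chain genes (median coding length 442.5 bases against 465) had a median of -0.012 (with plain CPM -0.33 against -1.34). Fewer cycling crypt cells cannot be told apart from the remaining explanations, since cell cycle genes had a median of -1.05 while the stem cell markers, whose members went both ways, had -0.13 (-0.57 to 0.23).

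Second, the 5 fibrillar collagens were lower in the fasted library (median -2.07). The 14 other fibroblast markers had a median of -0.86, and the collagens differed from it by -1.21 (bootstrap interval of the difference -2.81 to -0.74). Of these 14, 8 were lower, 2 (Dcn and Pdgfra) higher and 4 neither, and 0 of the 19 genes are in another list. Some of the 14, such as Vim and Sparc, are made by other cell types too, which would hide a loss of fibroblasts in their median. Fewer fibroblasts may therefore account for a part, and as the whole cause cannot be excluded by this gap. Long coding sequences or the GC share of collagens, each taken alone, are argued against. Of the lists matched on length 0 of 10000 were as low, and of those matched on GC share 0 of 10000. Codon and amino acid content were not matched.

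Last, of the 70 members of the hydrolase, transporter and lipid absorption lists 52 were higher in the fasted library and 2 lower (median 1.15). A larger share of villus enterocytes cannot be told apart from the other explanations. The median over these 70 lay above that of 18 genes of the microvillus and epithelial cytoskeleton (0.22) by 0.94 (bootstrap interval 0.52 to 1.27), past the bound of 0.5 set beforehand, but 8 of the 18, such as Epcam and Krt8, are made by other epithelial cells too, which would hide such a shift. Without those the median was 0.35 and the difference 0.80 (0.15 to 1.19), no longer clear of 0.5. A more proximal piece of intestine stays open too. The 7 distal ileum genes had a median of 0.92 (0.31 to 1.11), above 0 where this explanation needs it below, but with plain CPM the interval reached -0.0079. Fabp6, which is among the 7, had a log2 ratio below 0, as given with the bile acid genes.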
